A study of Mus musculus with 6 samples.

How the data were processed

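RNA from livers of male Lox control and SIRT1 LKO mice was pooled from 2 animals per replicate and 500 ng was labelled with Cy3, per the labels. The 6 arrays are 1-colour Agilent whole mouse arrays of 45018 spots. The animals are not known individually, so the replicate is a pool, and p-values measure the spread between arrays of 1 pool each. That spread lies within 1 slide for the controls, while LKO replicate 3 lay on another slide than LKO replicates 1 and 2. Groups and replicate numbers were taken from the sample titles.

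The scanner files hold spot intensity written by Agilent Feature Extraction 9.5, per the submitters' processing notes, with a processed intensity that was background-subtracted and spatially detrended within the array, per the file headers. The deposited value table holds 1 linear intensity per probe and array, made with an error model of the Rosetta Resolver software, per the labels. Set against the scanner files, its columns equalled the processed intensity in 5 samples, with neither centring nor scaling between arrays, and differed in LKO replicate 3 (median ratio 0.719, log2 correlation across probes 0.985). The medians of its columns were 74.5, 62.5 and 62.9 for the controls and 62.0, 62.5 and 62.6 for the LKO samples, in the order of the replicate numbers. What the authors did to the last column is not given in the sources used here. Other flags per spot (well above background, saturated, outlier) are 0 or 1 values deposited in the scanner files.

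Control spots were left out, outlier spots were set missing, and spots of 1 probe were averaged after log2. The 75th percentile of each array was subtracted. A probe was tested when it was well above background on all 3 arrays of at least 1 group, which kept 23591 probes. The probe with the highest mean over the 6 arrays stood for its gene, for 16512 genes. Gene names come from the accession in the scanner files matched without version to a RefSeq gene table of assembly GRCm38.p6, which matched 22951 of 41174 probes and renamed 5141. Other probes keep the name in the file. Coordinates are those of the files, on mm7. No genome sequence was used here, so the exon of a probe is not given.

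The genotype difference (LKO minus control) was fitted with limma 3.58.1 (lmFit and eBayes, genotype only) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and adjusted over 32 lists. Counts adjusted over the list alone use the limma p-values of its members. Camera with an estimated correlation and fry were run beside it. With an estimated correlation all 32 lists had the same camera adjusted p, 0.981 with all pools, 0.999 with the value table and 0.991 without LKO pool 3. Those values therefore do not tell the lists apart. Every list was chosen from textbook knowledge before the data were examined. Genes named in the text are Sirt1; the 10 largest rises and 10 largest falls past the threshold with complete separation of the groups, among genes with a symbol in the reference table, filled where fewer passed with the smallest p-values in that direction, given as values; the 3 members of each list with the smallest p and members past the threshold where 6 or fewer; and 19 genes of lipid and glucose metabolism, inflammation and hepatocyte identity named without regard to their result. Of the genes so chosen, 3 are not reported here. A gene not well above background on any array of a group is given as a bound.

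The steps were tested on simulated data made from the means and spreads of 16485 genes with 200 changed, in 20 simulations of 3 arrays against 3. The fit recovered 22.8% of 1.5-fold, 61.9% of 2-fold and 87.2% of 4-fold changes, none in the wrong direction, with a mean of 7.2 false calls. A list of 20 genes shifted by -0.4 was recovered in 20 of 20 simulations and 1 of 200 unshifted lists was called. These simulated genes vary independently.

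Alternatives were normexp background correction with an offset of 50, quantile normalization, centring on the median of tested probes, no filter on dim probes, a filter to probes above background on all 6 arrays, outlier spots kept, the mean of a gene's probes, every probe on its own, the slide as a random block, the replicate number as a block, an intensity trend with robust variance, array weights, the value table, each replicate left out, an unadjusted p under 0.01 with 1.5-fold, and a test against 1.2-fold. All were listed before the data were examined. Figures were drawn with matplotlib 3.10.9.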

Results

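The series measured liver gene expression in male mice on chow in which SIRT1, an NAD-dependent protein deacetylase, had been deleted in the liver (SIRT1 LKO), and in Lox control mice. The animals were 10 weeks old, had free access to food and were killed at 4 pm. RNA of 2 mice was pooled per replicate, so that 3 pools stood for the 6 mice of each group. Each pool was hybridised to a 1-colour Agilent whole mouse array with 41174 probes other than control spots. The 75th percentile of the intensity lay between 1005 and 1056 in 5 arrays and was 1289 in the third LKO array, and between 52.2% and 66.4% of probes were well above background. The number of arrays limits the precision. The 3 control pools lay on 1 slide, LKO pools 1 and 2 on a second and LKO pool 3 on another. Values below are log2 intensities relative to the 75th percentile of the array, given as mean ± SD with n = 3 per group. Tests are limma with Benjamini-Hochberg adjustment over 16512 genes unless another is named.

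For LKO pool 3 the deposited sources differed. In the other 5 samples the deposited value table equalled the scanner file within 1% for 99.8% of probes, whereas in LKO pool 3 it did so for 0.853%. The scanner files were used throughout, as fixed before the data were examined. Values with the value table or without this pool are given beside some results, not all. Which source holds LKO pool 3 is not settled by the files. By the SD over 21166 probes of the log2 difference, the value-table column lay nearest LKO pool 2 (0.342), then control pool 2 (0.395) and LKO pool 1 (0.407). The scanner array lay about as far from control pool 2 (0.428) as from LKO pool 2 (0.429) and LKO pool 1 (0.444).

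**Figure D1:**
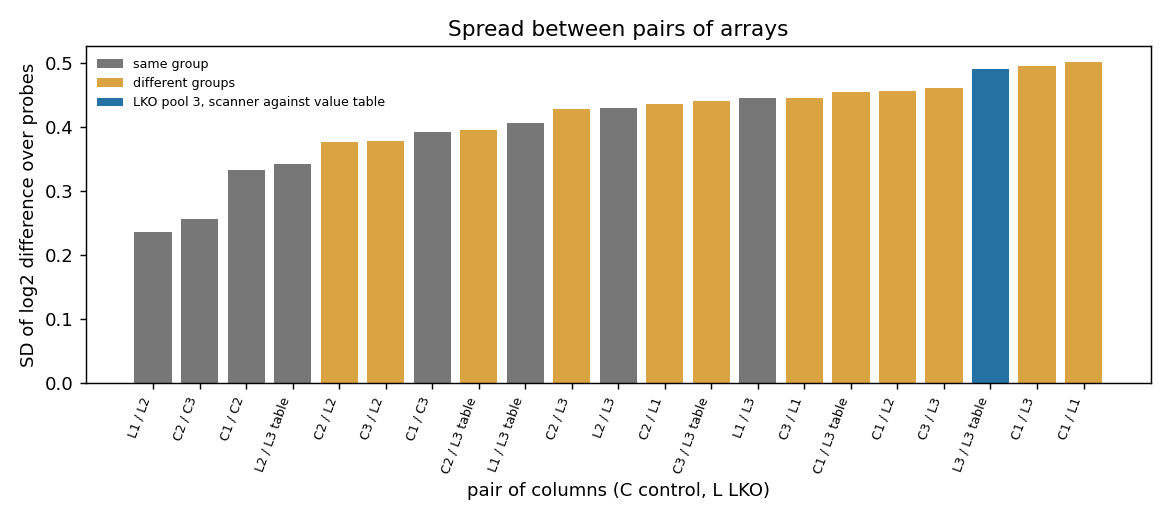
Spread between pairs of arrays as the SD over 21166 probes of the log2 difference (y axis, from 0) for each pair (x axis, C control, L LKO), grey for pairs of 1 group, yellow for pairs of different groups and blue for the LKO pool 3 sources. The blue bar stood at 0.491, between 0.461 and 0.495 of pairs from different groups, and the closest pair was LKO pools 1 and 2 at 0.235.

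The first question was whether Sirt1 transcript was lower in the LKO livers. Sirt1 signal was 0.30 ± 0.06 in the controls and 0.06 ± 0.12 in the LKO livers, 1.18-fold lower and lower in 3 of 3 LKO pools (log2 difference -0.24, SE 0.10, 95% interval -0.48 to 0.00, adjusted p = 0.237). The difference did not pass the threshold, and was -0.29 both with the value table (adjusted p = 0.105) and without LKO pool 3 (adjusted p = 0.120). This probe lies on chromosome 10 at 62855795 to 62855854 (mm7, minus strand). A dimmer Sirt1 probe at 62838289 to 62838348 differed by -0.02. The deleted exons are not given in the sources used here, so neither probe can be placed inside or outside the deleted part, and these values do not check the genotype labels.

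The central comparison asked which liver transcripts differed between the genotypes. Slc3a1, a subunit of a cystine and dibasic amino acid transporter, fell from 2.08 ± 0.08 to 0.40 ± 0.10, which is 3.19-fold (SE 0.10 on the log2 scale, adjusted p = 0.0213). Dct, dopachrome tautomerase of the melanin pathway, fell by 2.32 on the log2 scale (SE 0.17, adjusted p = 0.0213), and Serpine2, a serine protease inhibitor, fell 4.69-fold (SE 0.20, adjusted p = 0.0332). Osbpl3, an oxysterol-binding-protein relative, fell 3.11-fold, and Vnn1, a pantetheinase known as a PPAR-alpha target, fell 2.11-fold, from 2.90 ± 0.03 to 1.82 ± 0.07 (both adjusted p = 0.0213). Rbm3, a cold-inducible RNA-binding protein, rose 1.66-fold, from 3.65 ± 0.02 to 4.38 ± 0.03 (adjusted p = 0.0492), and Ap1s3, a clathrin adaptor subunit, rose 3.12-fold (SE 0.12, adjusted p = 0.0213) from a level well above background on 1 of 3 control arrays.

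In all, 24 of 16512 genes passed, 5 higher and 19 lower in the LKO livers. The rises were Ap1s3, Osbpl7 (log2 difference 0.81), Rbm3 and the transcripts C030016K15Rik and AK051598, the last 2 outside the rule for named genes and chosen after their values were seen. Among genes with a symbol in the reference table, the largest falls also held Adgrg2 and Pak6 (log2 differences -1.67 and -1.66), 4933416I08Rik (-1.56), the olfactory receptor Olfr382 (-1.27), the volume-regulated channel subunit Lrrc8e (-1.25) and the ephrin receptor Epha3 (-1.11). A second tested Osbpl7 probe differed by -0.11, opposite in sign to the one used, while second probes of Osbpl3 (-1.15) and Rbm3 (0.66) had the same sign as the first. Among rises short of the threshold, the smallest p-values belonged to Mmp7 (1.33, adjusted p = 0.053), Gstp3 (0.83) and Cdkn2c (0.80). Mmp7 was well above background on 1 of 3 control arrays. At an unadjusted p under 0.05 there were 3482 genes. In 4750 genes (28.8%) the 3 LKO values lay wholly above or wholly below the 3 control values, where chance gives 10% for 3 against 3 exchangeable arrays. The 3 controls share a slide that holds no LKO array, so an effect of that slide would also separate the groups.

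The count depended on single arrays. It was 0 when any one of the 3 control pools, LKO pool 1 or LKO pool 2 was left out (limma, 2264 to 3009 at an unadjusted p under 0.05), and 443 (241 higher, 202 lower) without LKO pool 3, among them all 24 genes. When LKO pool 3 was taken from the value table, 88 genes passed (50 higher, 38 lower), of which 11 were among the 24. Of the falls named above, Vnn1, Adgrg2, Pak6, 4933416I08Rik and Lrrc8e did not pass there. With the slide as a random block 0 passed in limma, with 1795 at an unadjusted p under 0.05. Each of these fits shares at least 5 arrays with the fit that gave 24 genes.

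**Figure D2:**
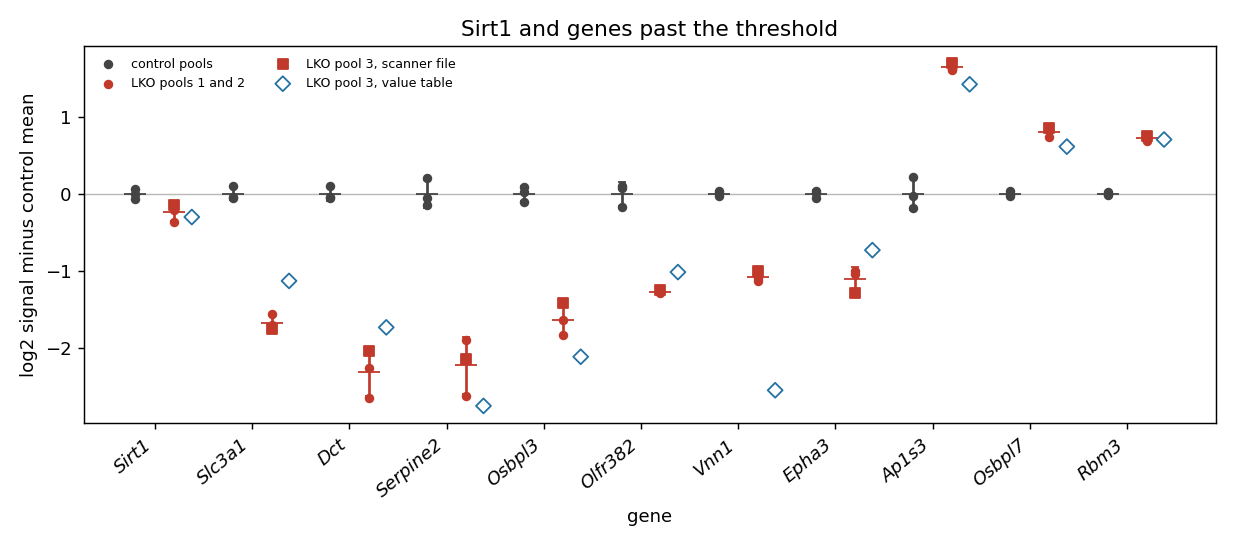
Signal of Sirt1 and of 10 genes past the threshold in each pool, as log2 signal minus the control mean (y axis) by gene (x axis), with horizontal marks and bars for group mean and SD (n = 3, scanner files); filled circles are pools, the filled square is LKO pool 3 from its scanner file and the open diamond the same pool from the value table, which is not in the mean. Vnn1 in LKO pool 3 was 1.90 in the scanner file and 0.34 in the value table, both below the control mean of 2.90.

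The animals were sampled to examine PPAR-alpha dependent metabolism, the nuclear receptor programme of fatty acid oxidation. Of the 39 PPAR-alpha targets tested, Vnn1 fell over all genes tested, and adjusted over the list alone 4 members fell (Vnn1, Pex11a, Hadha and Cidea, the last named after its value was seen) and Acot3 rose. In the same count 8 fell and 0 rose with the value table, and 6 fell and 2 rose without LKO pool 3. Pex11a, a peroxisome proliferation factor, differed by -0.68 (SE 0.09, adjusted p = 0.0582) and Acot3, an acyl-CoA thioesterase, by 0.78 (adjusted p = 0.0764). Acot3 differed by 0.06 with the value table, LKO pool 3 being at -0.48 there and at 1.66 in the scanner file. The omega-hydroxylases Cyp4a10 and Cyp4a14 differed by -0.76 (adjusted p = 0.127) and -0.84 (SE 0.64, adjusted p = 0.488), neither past the threshold. Ppara itself was 4.13 ± 0.21 in the controls and 4.13 ± 0.10 in the LKO livers. Cpt1a (0.23), Acadm (-0.15), Ehhadh (-0.30), Pdk4 (0.16) and Fgf21 (0.17) had adjusted p between 0.371 and 0.794. Cpt1a was -0.02 and Fgf21 -0.13 with the value table, 0.09 and 0.41 without LKO pool 3, and Ehhadh was -0.13 and -0.18 in the same order. As a list, 24 members were lower and 15 higher, with a median log2 difference of -0.11 (camera adjusted p = 0.0898).

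The PPAR-alpha list passed with the value table (camera adjusted p = 0.00348, 0.999 with an estimated correlation), where Cyp4a14 differed by -2.29 (adjusted p = 0.129) and Vnn1 by -1.59 (adjusted p = 0.0819), and not without LKO pool 3 (adjusted p = 0.161). Its adjusted p ranged from 0.000118 to 0.981 over 20 alternatives. Cyp4a14 in LKO pool 3 was 7.38 in the scanner file and 3.03 in the value table, against 6.16 and 4.70 in LKO pools 1 and 2.

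Other lipid lists did not pass. Mitochondrial beta-oxidation (median -0.01, camera adjusted p = 0.939) and peroxisomal beta-oxidation and biogenesis (0.06, adjusted p = 0.955) held no member past the threshold over all genes, with Hadha at -0.36. Adjusted over the list alone, the peroxisomal list held 1 fall, Pex11a, and 1 rise, Hacl1 (0.54), of which the rise ended without LKO pool 3. Of the 27 genes of fatty acid and triglyceride synthesis, 16 were higher and 11 lower, and none passed (median 0.09, camera adjusted p = 0.926). Fasn, fatty acid synthase, was 7.26 ± 0.43 in the controls and 7.75 ± 1.12 in the LKO livers, a difference of 0.49 (1.12 with the value table and 1.13 without LKO pool 3). Srebf1 differed by 0.05 and Scd1 by -0.09 (0.36 and 0.56 with the value table, 0.31 and 0.35 without LKO pool 3). With the value table this list rose (median 0.36, camera adjusted p = 0.0252, 0.999 with an estimated correlation), as it did without LKO pool 3 (median 0.31, adjusted p = 0.0307, 0.991 with an estimated correlation), over a range of 0.0252 to 0.985 among 20 alternatives. Adjusted over the list alone, 7 members rose with the value table, among them Pklr (0.71) and Pnpla5, and 13 rose and 1 fell without LKO pool 3. Cholesterol synthesis (camera adjusted p = 0.939), bile acid synthesis and transport (0.764), LXR targets and cholesterol efflux (0.926) and lipoprotein assembly and uptake (0.939) did not pass, and of their members Lpl, in the LXR list, fell adjusted over the list alone, though not with the value table. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by 0.31 (adjusted p = 0.597) and by -0.02 with the value table, and Akr1d1, of the same pathway, by 0.87 (adjusted p = 0.0877).

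**Figure D3:**
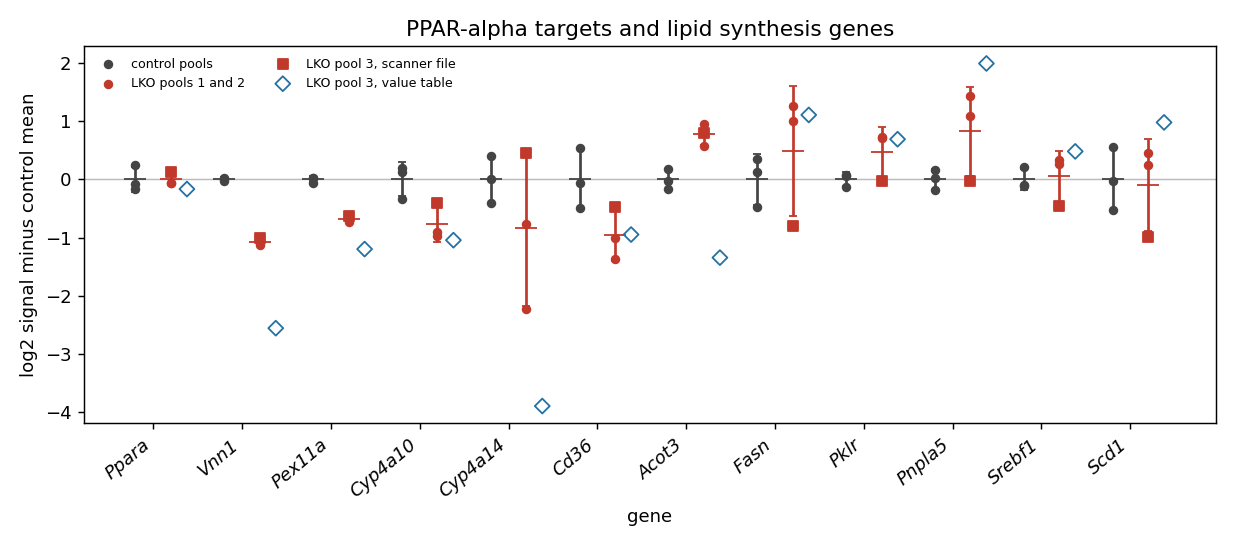
Signal of PPAR-alpha targets and lipid synthesis genes in each pool, as log2 signal minus the control mean (y axis) by gene (x axis), with the same symbols: bars are SD around the group mean (n = 3, scanner files) and the open diamond is LKO pool 3 from the value table. The LKO pool 3 sources gave 7.38 and 3.03 for Cyp4a14 and lay on opposite sides of the control mean for Fasn, at 6.46 in the scanner file and 8.37 in the value table.

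Of the 32 gene lists fixed before the data were examined, 2 passed. Genes that are more abundant in male than in female liver fell, with 18 of 19 members lower and a median log2 difference of -0.25 (camera adjusted p = 0.00038, 0.981 with an estimated correlation). No member passed over all genes, and 3 fell adjusted over the list alone, namely Susd4 (-1.25), the major urinary protein Mup5 (-0.75) and the carboxylesterase Ces2e (-0.69), of which Mup5 (-0.54) did not pass with the value table. The call ended without LKO pool 3 (median -0.13, adjusted p = 0.0625) and held with the value table (median -0.12, adjusted p = 0.0252, 0.999 with an estimated correlation), within a range of 1.08e-08 to 0.981 over 20 alternatives. Female-biased genes did not pass (median 0.03, camera adjusted p = 0.939). In that list Cux2 was well above background on the LKO arrays and on no control array, at least 1.09-fold higher. The bound sets the LKO mean against the higher of the dim probe's signal and the lowest signal well above background on each control array. Its limma adjusted p of 0.0711 belongs to the difference from the dim control signals, not to the bound. Cyp2b13 differed by -1.73 (adjusted p = 0.122). Adjusted over the list alone, 2 female-biased genes rose (Cux2 and Acot3) and Cyp2b13 fell. Of these 3, 0 passed with the value table, and without LKO pool 3 the 2 rises passed and Cyp2b13 did not.

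Adipose tissue markers also fell, with 6 of 7 tested members of a list of 12 lower and a median of -0.57 (camera adjusted p = 0.048, 0.981 with an estimated correlation). No member passed over all genes, and adjusted over the list alone 4 fell (Lpl, Cfd, Cd36 and Car3) and Fabp4 rose, Car3 and Fabp4 being named after their values were seen. Lpl, lipoprotein lipase, differed by -1.01, Cfd (adipsin) by -3.44 with SDs of 1.17 and 1.45, and the fatty acid transporter Cd36 by -0.95. Second tested probes of Lpl and Cd36 differed by -0.49 and -0.73. With the value table the Lpl probe used differed by -0.44 and did not pass. LKO pool 3 lay at 1.49 there, above all 3 controls, and at -0.22 in the scanner file. Cfd was well above background on 2 of 3 LKO arrays and differed by -2.65 without LKO pool 3. Cd36 also belongs to the PPAR-alpha list. The list call ended without control pool 2 (adjusted p = 0.0545) and held with the value table (adjusted p = 0.0252, 0.999 with an estimated correlation) and without LKO pool 3 (adjusted p = 0.0435, 0.991 with an estimated correlation).

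Lists for the cell types of the liver did not pass with all pools. Hepatocyte identity genes had a median of 0.10 (camera adjusted p = 0.939), with Alb at 8.93 ± 0.19 in the controls and 9.10 ± 0.25 in the LKO livers. Kupffer cell and macrophage markers were lower in 18 of 20 tested members (median -0.19, adjusted p = 0.184) and lymphocyte markers in 12 of 18 tested members (median -0.18, adjusted p = 0.184). With the value table the medians of these 2 lists were 0.20 and 0.17. Pancreas markers were lower in 8 of the 8 tested members of a list of 20 (median -0.33, camera adjusted p = 0.060). Without control pool 3 the Kupffer cell (adjusted p = 0.000431), lymphocyte (0.0327) and pancreas lists (0.0426) passed as lower, as pancreas markers did without LKO pool 1 (0.0260) and LKO pool 2 (0.0412). After normexp the Kupffer cell list passed (0.00375). With all pools and an estimated correlation the adjusted p of each was 0.981. The stellate cell and matrix list (adjusted p = 0.764) held Col4a2 (-0.93), Col4a1 (-0.70) and Timp2 (-0.65), which fell adjusted over the list alone. In that count 0 members fell with the value table and 4 without LKO pool 3. In the cholangiocyte list (adjusted p = 0.955) Sox9 differed by -1.12 and Pkhd1 by -0.43. Prom1, well above background on 1 of 3 control arrays, differed by 0.81. These 3 passed adjusted over the list alone. There were 4 rises and 0 falls in that count with the value table, which had Sox9 at -0.65, and 4 rises and 2 falls without LKO pool 3. Endothelial (0.955), neutrophil (0.926), and erythroid and platelet (0.955) markers held no member past the threshold.

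Glucose, mitochondrial and clock genes were also measured. In gluconeogenesis and glucose metabolism 18 of 25 members were higher (median 0.06, camera adjusted p = 0.689). Pck1 differed by -0.03 and G6pc by 0.48 (adjusted p = 0.392), while the transaminases Got1 (0.77) and Gpt2 (0.42) and the kinase Sik1 (1.55) had adjusted p of 0.103 to 0.126. Oxidative phosphorylation (median 0.02, adjusted p = 0.939) and regulators of mitochondrial biogenesis (0.00, adjusted p = 0.939) did not pass. The latter list held 0 members past the threshold adjusted over the list alone, 1 rise and 3 falls with the value table, and 3 rises and 4 falls without LKO pool 3. In it Ppargc1a, the coactivator PGC-1alpha, differed by -0.75 (SE 0.30, adjusted p = 0.222), and Esrra by 0.49 (adjusted p = 0.0999). The circadian clock and output list (adjusted p = 0.805) held 4 rises and 1 fall adjusted over the list alone, 7 and 3 with the value table, and 1 and 0 without LKO pool 3. Its lowest p-values were those of Nampt (0.46) and the repressor Nr1d1 (-1.26). In sirtuins and NAD metabolism (adjusted p = 0.955) no member passed.

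Stress, immune and growth lists did not pass either. NRF2 antioxidant targets (median 0.02, camera adjusted p = 0.955) held 2 falls adjusted over the list alone, Gclc, the catalytic subunit of glutathione synthesis (-0.85, adjusted p = 0.0696 over all genes), and Gpx2 (-0.46). Gpx2 differed by -0.32 with the value table and did not pass, and 1 member rose. In the ER stress and integrated stress response list (median -0.10, adjusted p = 0.523) Asns differed by -2.26 (SE 0.61, adjusted p = 0.125) and Trib3 by -0.82, and the control value of Asns was 3.31 in pool 3 against 1.34 and 0.96 in the others. NF-kappaB targets (adjusted p = 0.955) held 2 rises and 2 falls adjusted over the list alone, with Nfkb1 at 0.43, Il1rn at -0.98 and Cxcl1 at -0.80 (-0.45 with the value table, where it did not pass); Tnf was not well above background in either group. Acute phase proteins (0.764), p53 targets (0.955), CAR and PXR xenobiotic metabolism (0.955) and the cell cycle (0.939) did not pass. In the cell cycle list Cdk1 differed by -0.62 (adjusted p = 0.071) and Ccne2 by 0.77 (adjusted p = 0.101), both past the threshold adjusted over the list alone. The cell cycle list rose with the value table (median 0.25, camera adjusted p = 0.0389, 0.999 with an estimated correlation), with 4 rises and 0 falls adjusted over the list alone, and Cdk1 differed by -0.42. Other lists with 0 members past the threshold in that count also gained some with the value table, among them 5 rises and 4 falls in the ER stress and integrated stress response, 4 and 1 in gluconeogenesis and glucose metabolism, and 5 and 1 in hepatocyte identity. The median, the mean and the camera direction differed in sign for mitochondrial beta-oxidation, regulators of mitochondrial biogenesis, NF-kappaB targets, CAR and PXR xenobiotic metabolism, NRF2 antioxidant targets, the cell cycle, cholangiocyte markers, and erythroid and platelet markers, none of which passed.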

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

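In this part the 3 tests of the LKO pool 3 sources and the spike-in comparison were chosen only after the result was seen. Groups of 3 were not tested for outlying samples.

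The value table, used in the report only as an alternative, holds a column for LKO pool 3 that departs from the scanner file of the same sample. Over 21166 probes well above background on all 6 arrays, 1080 probes were over 2-fold apart between the sources, against 122 to 535 between arrays of 1 group that leave pool 3 out. The SD of the log2 difference was 0.491, above the 0.392 of the most distant pair of control arrays, which argues against another scan or other processing of 1 hybridisation. Over genes chosen from LKO pools 1 and 2 against 2 controls, the difference from the held-out control followed the LKO change with a slope of at least 0.379 in the scanner file and 0.445 in the value table. That leaves a control sample open in either source, since the controls that chose the genes and the held-out control share a slide and the LKO pool 3 scanner array lies on another. Other RNA, such as another LKO pool or animals of another genotype not analysed here, stays open and may account for the gap of 0.491, and no biological explanation was tested.

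The second pattern is the count of genes, 24 with all pools and 443 without LKO pool 3, on slides that each hold 1 genotype. Of genes chosen at an unadjusted p under 0.01 from LKO pools 1 and 2 against 2 controls, at least 71.5% kept their direction in the LKO pool 3 scanner array, on another slide, minus the held-out control. That argues against the slide of LKO pools 1 and 2 as the only source of these differences. The share that this slide accounts for is not settled, since the slope in that array was as low as 0.379. The control slide is also common to the choosing and held-out controls. The slide of the 3 controls cannot be told apart from the control genotype, since no other array shares it, and spike-in probes differed by up to 0.381 in size between the groups after scaling, with LKO pool 3 the lowest array for all 10. With the slide as a random block (consensus correlation 0.327) limma called 0 genes and 1795 had an unadjusted p under 0.05. With genotype in that fit, only LKO pool 3 against LKO pools 1 and 2 compares slides within a group. The correlation therefore cannot tell a slide effect from any other difference of the LKO pool 3 array.

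The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 24 genes, as many as 1 of the 10 splits counting itself, and the highest of the other splits gave 0. For gene lists the real split gave 2 and all 10 splits gave at least as many, with 16 in the highest other split, which sets control pool 1 with LKO pools 2 and 3. Whether these counts come from a structure among the samples or from the preset correlation of camera was not tested.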

How the results depend on the processing

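Among the alternative fits with 1 value per gene, 24 of 24 genes kept their direction in each except the filter to probes above background on all 6 arrays. That filter tested 21 of them, all in the direction reported. For several fits this agreement was fixed in advance. Genes with complete separation of the groups cannot change direction when 1 array is left out or arrays are weighted. The replicate block and the intensity trend leave a difference unchanged where no value is missing. Probe by probe, a second Osbpl7 probe had the opposite sign (-0.11). The calls were less stable. Causes were not tested. Array signal over background limits dim genes, and without the filter on dim probes 28784 genes were tested.

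Genes past the threshold (higher and lower) were 24 (5 and 19) as reported, 12 (2 and 10) after quantile normalization, 13 (1 and 12) after centring on the median of tested probes, 13 (1 and 12) with outlier spots kept, 24 (3 and 21) with the mean of a gene's probes, 66 (11 and 55) with probes above background on all 6 arrays, 68 (19 and 49) with an intensity trend and robust variance, 5639 (3209 and 2430) with array weights, which gave LKO pool 3 a weight of 0.212, and 88 (50 and 38) with the value table. They were 15, 1 of them higher, with every probe on its own, 659 (263 and 396) at an unadjusted p under 0.01 and 1.5-fold, and 10 (1 and 9) in the test against 1.2-fold. In limma they were 0 (0 and 0) after normexp with 1159 at an unadjusted p under 0.05, 0 (0 and 0) without the filter with 4777, and 0 (0 and 0) with the slide as a random block with 1795. Leaving out 1 replicate gave 0 to 443 (0 to 241 higher, 0 to 202 lower), with 2264 to 3009 at an unadjusted p under 0.05 in the 5 fits that called 0.

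Nothing in the labels says that the replicate numbers pair the pools. The deviations of same-numbered pools correlated at -0.00356, -0.0555 and -0.104, against -0.0715 to 0.128 for pools of different numbers. These values show no sign of pairing and cannot exclude it. The replicate block gave 0 genes (0 and 0) and 2964 at an unadjusted p under 0.05.

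Lists past the threshold were 2 as reported, 9 after normexp, 0 without the filter, 1 with probes above background on all 6 arrays, 1 with the mean of a gene's probes, 5 with the value table, 0 with an estimated correlation, 0 in fry's directional test, 14 in fry's mixed test, and 1 to 5 with 1 replicate left out. The slide block and the replicate block added pancreas markers (adjusted p = 0.0493 and 0.0337). PPAR-alpha targets had an adjusted p of 0.000118 after normexp, 0.0158 with array weights, 0.00348 with the value table and 0.0144 to 0.334 with 1 replicate left out. Male-biased genes had 0.0586 without the filter, 0.167 with array weights, 0.981 with an estimated correlation, 0.534 in fry's directional test and 1.26e-05 to 0.0625 with 1 replicate left out. Adipose markers had 0.173 without the filter, 0.167 with probes above background on all 6 arrays, 0.0627 with the mean of a gene's probes, 0.981 with an estimated correlation, 0.288 in fry's directional test and 0.0175 to 0.0545 with 1 replicate left out. Oxidative phosphorylation turned from higher to lower after normexp (0.0304), and the cell cycle from lower to higher with the value table (0.0389).

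Sirt1 passed only with array weights (-0.29), over a range of -0.29 to -0.13 in 18 alternatives. Among the other named genes, 1996 values kept their side of the threshold, 150 lost and 129 gained it, none past the threshold changed sign, and 31 values short of it on both sides did.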

Other observations

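In this part the tests of scaling, of LKO pool 3 and of hepatocyte RNA for the male-biased list were chosen only after the result was seen.

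Some xenobiotic and acute phase genes differed without passing the threshold. Cyp2b10, a target of the receptor CAR, differed by -2.27 (SE 0.61, limma adjusted p = 0.126) and by -1.24 with the value table, LKO pool 3 being at -2.84 in the scanner file and 0.22 in the table, and Gstm2, a glutathione transferase, was 4.08 ± 0.32 in the controls and 4.83 ± 0.20 in the LKO livers (SD, limma adjusted p = 0.116). Among acute phase proteins Cp, ceruloplasmin, differed by -0.50 (adjusted p = 0.127) and Lcn2, lipocalin 2, by 0.74 (adjusted p = 0.143). Without LKO pool 3, Cp fell by 0.63 (adjusted p = 0.0478).

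The fall of the male-biased liver genes is the third pattern weighed. Differences in the intensity distribution between arrays are argued against as the whole of it, since the camera adjusted p after quantile normalization was 0.00035. Hepatocyte identity genes had a median of 0.102 (SE 0.0489, over the genes of the list and not over pools) where the male-biased list had -0.254. These medians argue against a loss of hepatocyte RNA that lowers both lists alike. They cannot show whether hepatocyte RNA was lost, since each array was scaled to a percentile that such a loss may also lower. The part played by LKO pool 3 stays open: the adjusted p was 0.0625 without it and 0.0252 with its value-table column. With an estimated correlation the adjusted p was 0.981, the same value as for every other list, so it says nothing particular to this list. Whether these genes move together between pools for reasons other than genotype was not tested and stays open. A biological difference in sex-biased expression stays an untested hypothesis.

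DNA carried over from the strain of the floxed allele could place changed genes near Sirt1. On chromosome 10, 14 of 771 genes (1.82%) had an unadjusted p under 0.001, against 1.33% elsewhere (Fisher's exact test, two-sided, adjusted p = 0.979 over 20 chromosomes). The share was higher but within chance, so the test left the hypothesis open.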
